A study of Drosophila melanogaster with 2 samples.

How the data were processed

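The samples were chromatin immunoprecipitations followed by sequencing (ChIP-seq) with an anti-GFP antibody on whole Drosophila melanogaster prepupae, aged 1 day, from a transgenic line that expressed the protein CG11294 fused to eGFP. The label for the antibody named CG11294 while the description named anti-GFP; the description was followed here, and which protein the antibody recognised was not tested. The labels gave 2 biological replicates of this 1 group, with chromatin fragmented by sonication. No control immunoprecipitation, input or other stage was analysed here, so no comparison between conditions was made.

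The deposited data used here were peak lists on genome build dm6, per the labels and the text listings deposited with them. The aligner, the peak caller, their versions and the read depth were not given in the sources used here. For each replicate there was a ranked list of relaxed peaks and a shorter thresholded list. For the series there were 2 ranked lists with their thresholded lists, one from IDR (irreproducible discovery rate, a measure of rank agreement) between the replicates and the other from the pooled analysis. The deposited signal value of each peak was the authors' enrichment statistic; its scale was not given, and it was used only to rank, filter and describe peaks within a list. The deposited −log10 of the global IDR was used to find which ranked peaks lay past the thresholds. Every peak of the 4 thresholded lists was found in its ranked list, with an IDR value under 0.01. The series ranked lists also hold 8 columns each with the positions and values of the list's inputs. These columns served only to tell the 2 ranked lists apart, and for all results the replicates' own lists were read instead. Which ranked list came from IDR between the replicates was not stated in the file names; it was inferred by comparing the positions and signal in those columns with the replicates' lists, and checked by matching each thresholded list to its ranked list.

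The main list was the thresholded list of IDR between the replicates, restricted to chromosome arms 2L, 2R, 3L, 3R, 4 and X. Peaks on Y and unplaced contigs were left out of the comparisons. Background peaks were the relaxed peaks of the same ranked list that overlapped no peak of either thresholded series list, and they numbered 92304. The peak ends in the files lay within the chromosome lengths of the Release 6 genome sequence, which was used for sequence, and genes came from the Ensembl annotation of the same release without transposable elements. The nearest annotated transcription start site (TSS) was found for each summit. A summit within 500 bp of a TSS was called a promoter summit, and the others were classed by position in the order 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic.

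Replicate overlap was the share of replicate 1 thresholded peaks that overlapped a replicate 2 thresholded peak by 1 bp or more, set against 1000 seeded draws of as many peaks from the other replicate's ranked list. Shares carry 95% Wilson intervals, which cover counting error over peaks only. Positions were tested against background peaks with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the 7 classes. The 17 motifs and the 2080 strand-collapsed 6-mers were searched on both strands in the 200 bp around each summit and in a window of the same size centred 500 bp to the left, and compared with two-sided exact McNemar tests adjusted within each family. A 6-mer was called with an adjusted p under 0.05 and a centre to flank ratio of at least 1.5 or its inverse. For the 14 gene lists, a gene was bound with a main-list summit within 1000 bp of a TSS, and tested genes were the 12941 with any relaxed peak in that window; two-sided Fisher's exact tests were adjusted over the 14 lists. Neighbouring genes can share a peak and peaks near each other share sequence, so neither genes nor peaks are independent replicates, and p-values measure spread over peaks or genes, not between animals.

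The main list, the tests, the gene lists and most alternative settings were fixed before the data were examined. Named genes were those with a TSS nearest to the 15 strongest main-list peaks found in both replicates' thresholded lists, up to 4 bound members of each list with the highest signal (up to 10 for the homeobox and ecdysone lists), the 10 genes with the most summits from 2000 bp upstream to the gene end, and CG11294. Named words were the 6 called 6-mers with the largest ratio. Names outside this rule are said to be so where they appear. The symbols Eip71CD, Eip55E, Eip63F-2, phm, Unc-89, Pdlim, Dl, dad and Hsp67Bb were not matched in the annotation and those list members were not analysed here. The alternative settings were the pooled list, each replicate's list alone, the strongest 1630 peaks of the main list, other windows, flanks, overlaps and backgrounds, GC-matched background peaks, and peaks away from promoters. Alternatives chosen after seeing the data were IDR values of 0.001 and 0.05, peaks past the IDR value put back (fixed beforehand for the peak count alone), a signal of at least 10, a list of mitochondrial ribosomal protein genes, and summits over gene bodies against 10000 length-matched draws.

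The word scan and the list test were tested on simulated data. With the 2 flanks of each real peak compared in random order, 0 of 2080 6-mers passed the adjusted p. The flanks had like GC content (43.0% and 42.9%) while summits had 35.7%, so this does not cover calls that follow from composition. Of 40 words written into 5% of windows, 36 were recovered, and all 40 at 10%. Whether the recovered words also reached the centre to flank ratio required for a call was not recorded. These counts therefore do not show how many of the planted words would be called. Random gene lists were called in 0.143% of 1400 draws. With 40% of members bound, all lists of 25 or more tested genes were called, and 83.3% of the smaller ones. The bound count of a list was the same in every draw, and all 14 lists were planted together. These shares therefore show which list sizes can pass, and are not rates of detection for a single bound list among unbound ones. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.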

Results

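Sites recovered by anti-GFP ChIP-seq were mapped in 2 biological replicates of whole prepupae. The prepupae expressed tagged CG11294, a paired-like homeodomain protein by its annotation. The question was where in the genome these sites lay, and near which genes and sequences. Without a control, recovery that did not need the tagged protein could not be told apart. A gene called bound is therefore one with a main-list summit near a TSS. The thresholded lists held 3229 peaks in replicate 1 and 2709 in replicate 2, and the list that rests on agreement between them held 3261, of which 3260 lay on the 6 main chromosome arms. The authors' signal value in that main list ranged from 2.02 to 1648.54 with a median of 110. The most common peak width was 340 bp, held by 2110 peaks, each with its summit at the midpoint. Of the 84 peaks with a signal under 10, 82 had another main-list summit within 400 bp, so most of the weakest peaks lay beside other peaks. Overlapping peaks merged into 3090 regions. Read depth was unknown. Below, positions are given relative to the TSS, with negative values upstream.

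Most of the 15 strongest sites, all of them found in both replicates, lay just upstream of a TSS. The peak of highest signal (1648.54) covered 3L 19590457 to 19590774, with its summit at -90 bp from the TSS of CG14100 (FBgn0036889). The second (signal 1634.37) covered X 2703720 to 2704054, at -29 bp from the TSS of Ugalt (FBgn0024994), a UDP-galactose transporter gene. Other strong promoter sites were those of mRpL41, a mitochondrial ribosomal protein gene (signal 1292, summit at -126 bp), Tcs5 (signal 1301, -105 bp), CG7601 (signal 1281, -105 bp) and PNPase, an RNA-degrading enzyme gene (signal 1158, -81 bp). Art3, an arginine methyltransferase gene (signal 1129), CenG1A (signal 1081) and CG18549 (signal 999) had summits at -121, -113 and -123 bp. The site of Art3 also lay at -136 bp from the TSS of mRpS10, and that of CenG1A at -379 bp from the TSS of mRpS23, so these genes share peaks; both were named after their values were seen. The noncoding genes lncRNA:CR44619 (signal 1190, -457 bp) and asRNA:CR45928 (signal 1049, 80 bp) were nearest to promoter peaks of this group. The others lay away from promoters. CG11050 held an intronic summit 1025 bp downstream of a TSS (2L 6612449 to 6612940, signal 1342). The summit nearest to CG16753 was 5716 bp downstream of its TSS (signal 1007), past the end of that gene and in an intron of another. Those nearest to CG13323 and CG31668 were intergenic, at 11915 bp (signal 1089) and 3760 bp (signal 1048). Around the CG14100 summit, 3L 19590594 to 19590634 read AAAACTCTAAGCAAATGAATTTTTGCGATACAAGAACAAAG, and around the Ugalt summit, X 2703861 to 2703901 read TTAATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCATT.

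The replicates shared many of their sites. Of 3217 replicate 1 peaks on the arms, 1763 (54.8%, interval 53.1% to 56.5%) overlapped a replicate 2 peak, and of 2708 replicate 2 peaks, 1770 (65.4%) overlapped one of replicate 1. With an overlap of 50% of both peaks the shares were 44.0% and 52.5%. As many peaks drawn from replicate 2's ranked list gave 3.32% on average and 4.66% at most in 1000 draws (one-sided p = 0.001, the smallest these draws can give in this permutation test). The draws ignored signal. They therefore show only that thresholded peaks coincide more than relaxed peaks at large, and not why. Of the main-list peaks, 1788 (54.8%) overlapped a thresholded peak in both replicates' own lists and 402 in neither. Across the 3200 main-list peaks with a ranked peak in both replicates, the signals correlated with a Spearman rho of 0.574; this is across peaks, which are not replicates.

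Promoters held 1168 of the 3260 summits (35.8%, interval 34.2% to 37.5%), against 14.2% of background peaks (odds ratio 3.37, Fisher's exact adjusted p = 4.11e-198). The main-list summits were upstream-biased, with 954 of the 1168 promoter summits (81.7%) upstream of their TSS against 41.5% in the background. Their median position was -130 bp, against 64 bp for background promoter summits. A band from 50 to 150 bp upstream, chosen after the profile was seen, held 375 summits, 11.5% of the list against 1.63% of the background (odds ratio 7.84, Fisher's exact p = 3.53e-174). Introns held a further 1552 summits (47.6% against 36.4%, odds ratio 1.59, Fisher's exact adjusted p = 1.75e-37). Intergenic sites were fewer than in the background (13.9% against 22.9%, Fisher's exact adjusted p = 1.61e-36). Coding exons, which held 22.7% of background peaks and made up 13.7% of the arms outside promoters, held only 9 main-list summits (0.276%). Background summits had a higher mean GC content than main-list summits (47.5% against 35.7%). Positions were not compared with GC-matched peaks, so part of these differences may follow from composition. Outside promoters, 5′ UTR and 3′ UTR summits were also fewer (0.460% against 0.985% and 0.675% against 1.98%, Fisher's exact adjusted p = 0.00158 and 2.64e-09). Other exons held more (1.26% against 0.855%, odds ratio 1.48, Fisher's exact adjusted p = 0.0206).

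**Figure D1:**
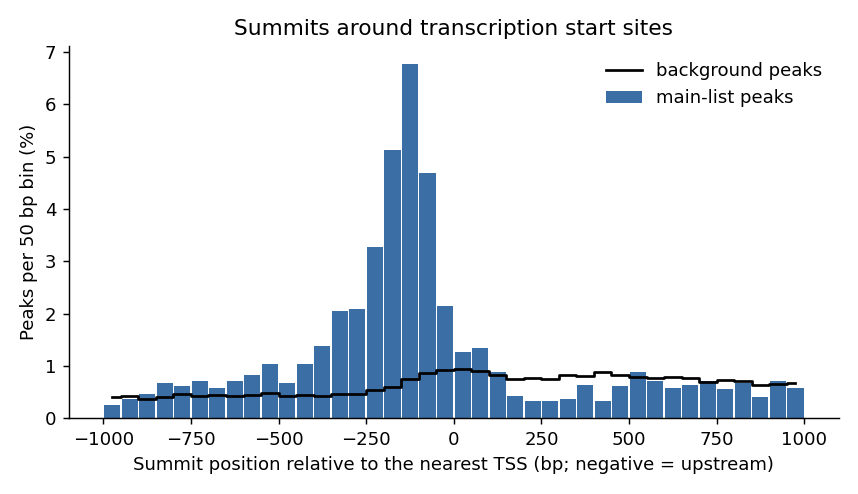
Percentage of main-list peaks (bars) and background peaks (line) per 50 bp bin of signed distance from the summit to the nearest TSS, within 1000 bp. The highest main-list bin, 100 to 150 bp upstream, holds 221 summits (6.78%), against 0.744% of background peaks.

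Stronger peaks lay at promoters more often. Of the 815 peaks of highest signal 50.3% were at promoters (interval 46.9% to 53.7%), against 30.8% of the 815 of lowest signal (27.7% to 34.1%), a difference of 19.5 percentage points (two-sided Fisher's exact p = 1.24e-15). The groups of 815 in between had 32.3% and 29.9%. Introns went the other way, with 39.1% of the 815 strongest and 50.2% of the 815 weakest peaks (Fisher's exact p = 9.05e-06).

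Chromosome X held 639 summits (19.6%, interval 18.3% to 21%) against 18.4% of background peaks, a difference that did not pass the test (odds ratio 1.08, two-sided Fisher's exact p = 0.0766). Summits were placed at 25.1 per Mb on 2L, 21.7 on 2R, 26.0 on 3L, 23.3 on 3R and 27.1 on X, with 1 summit on chromosome 4. The X difference passed the test in the pooled list (19.4%, Fisher's exact p = 0.000485), in each replicate's list alone, among the strongest 1630 peaks and at an IDR value of 0.001, and its direction turned at an IDR value of 0.05 (18.1%); both IDR values were chosen after seeing the data.

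Homeodomain sites were more frequent at summits than in the flank, but were not detectably more frequent than at background peaks of like GC content. The paired-class dimer site TAATNNNATTA occurred within 100 bp of 90 summits (2.76%, interval 2.25% to 3.38%) against 1.47% of flank windows (ratio 1.88, exact McNemar adjusted p = 0.000611). The core TAATTA occurred at 536 summits (16.4%) against 12.2% (ratio 1.35, exact McNemar adjusted p = 4.77e-06), the spacer variant TAATNNATTA at 84 against 34 (ratio 2.47, adjusted p = 8.21e-06), and the shorter site TAAT at 92.3% against 79.7%. Against GC-matched background summits, TAATTA stood at 16.4% and 17.7% (ratio 0.927, Fisher's exact adjusted p = 0.224), and TAATNNNATTA at 2.76% and 2.38% (ratio 1.16, adjusted p = 0.385). TAATNNATTA (ratio 1.24, Fisher's exact adjusted p = 0.224) and TAAT (92.3% against 90.8%, ratio 1.02, adjusted p = 0.0549) were higher there but did not pass the test. Against the flank, neither TAATTA nor TAATNNNATTA passed the test in replicate 2's list alone (ratios 1.46 for the dimer and 1.08 for TAATTA). Neither passed at peaks away from promoters (1.58 and 1.14). Within 50 bp of the summit the dimer did not pass (1.59, exact McNemar adjusted p = 0.0693), while TAATTA did (1.55, adjusted p = 1.07e-06). Both passed among the strongest 1630 peaks (dimer 1.84 and TAATTA 1.52, exact McNemar adjusted p = 0.0215 and 3.9e-06). The difference of TAATTA with strength did not pass the test in the main list, at 17.3% of the 815 strongest and 14.2% of the 815 weakest peaks (difference 3.07 percentage points, two-sided Fisher's exact p = 0.103). It passed in the pooled list (6.84, Fisher's exact p = 1.02e-05), at an IDR value of 0.05 (4.60, p = 0.00196) and between the 1630 strongest and the other peaks (2.82, p = 0.0334), and was 0 in replicate 2's list alone. The shorter site TAAT was more frequent at the 815 strongest peaks (94.2% against 88.0%, Fisher's exact p = 1.14e-05), which were also more often under 40% GC (82.6% against 61.0%).

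Summit windows were AT-rich, with a mean GC content of 35.7% (SD 7.0 over 3260 peaks) against 43.0% in the left flank and 47.5% at background summits. Of the 17 motifs, 7 were more frequent at summits and 5 less. Beyond the homeodomain sites, the TATA box word TATAAA (35.9% against 19.6%), the DNA replication-related element TATCGATA (43 summits against 8 flanks, ratio 5.38, exact McNemar adjusted p = 2.92e-06) and the tract AAAAAAAA (16.3% against 12.2%) were more frequent. The CA repeat CACACACA (3.62% against 7.94%), the GAGA repeat GAGAGAG (3.74% against 5.52%), the E-boxes CACCTG and CAGCTG, and the grainyhead-like site AACCGGTT were less frequent. Sites of Zelda, GATA factors, AP-1, TCF and nuclear receptors did not pass the test. With GC-matched background summits in place of the flank, 1 motif was higher, the GAGA repeat (3.74% against 2.36%, ratio 1.58, Fisher's exact adjusted p = 0.00211), and 1 lower, the tract AAAAAAAA (16.3% against 19.3%).

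In the scan of all 6-mers, 216 were called higher at summits and 557 lower. The 6 of largest ratio were AGTGTA (18.9% against 7.15%, ratio 2.64), GTGCAC (10.6% against 4.17%, ratio 2.54), ACAGTG (683 summits, against 8.34% of flanks, ratio 2.51), ACACTG (619 summits, against 7.85%, ratio 2.42), ATATTA (34.4% against 15.5%, ratio 2.22) and ACTGTA (15.6% against 7.09%, ratio 2.21), with exact McNemar adjusted p from 5.14e-22 to 8.39e-67. Words made only of A and T made up 30 of the 216. Against GC-matched background summits 31 words were higher and 36 lower. Of the 6 named words 5 were among the 31, led by ACAGTG (683 summits, against 9.39% of background summits, ratio 2.23, Fisher's exact adjusted p = 1.23e-50), and 7 of the 31 held CACTG on either strand. Overlapping words are not independent. In replicate 2's list alone 76 words were higher, and in replicate 1's list alone 294.

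**Figure D2:**
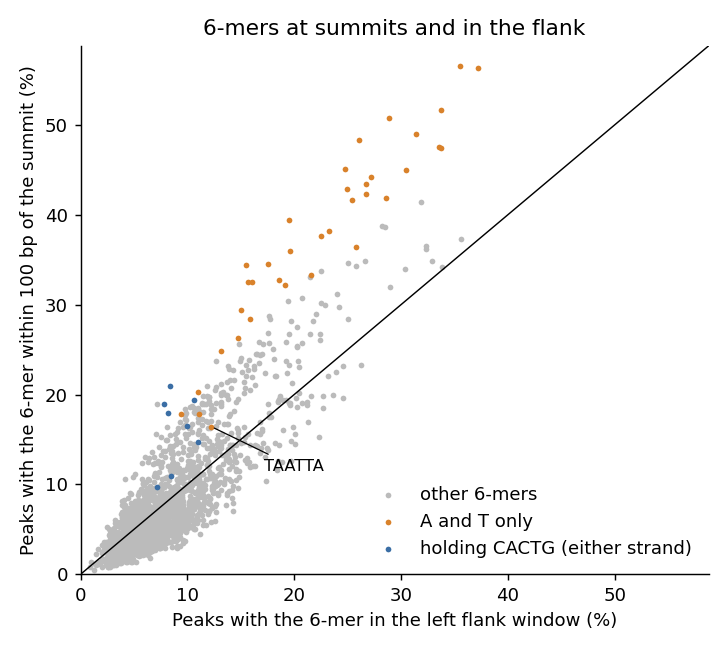
Each point is a 6-mer, with the percentage of main-list peaks that hold it in the left flank window (x axis) and within 100 bp of the summit (y axis); the line marks equal shares. Words of A and T only lie above the line, with TAATTA the lowest of them in ratio at 1.35, and ACAGTG has a ratio of 2.51.

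The CACTG word was more frequent beside the listed summit than at it. In the 2110 peaks of 340 bp the listed summit was the midpoint, and whether read density was highest there is not known. It occurred within 100 bp of 1715 summits (52.6%, interval 50.9% to 54.3%) against 31.1% of flank windows, a comparison made after the word scan was seen. Per 25 bp and 100 peaks there were 5.78 occurrences within 50 bp, 12.3 in the next 3 bins on either side, and 5.21 beyond 250 bp. TAATTA had the opposite shape, with 2.84 within 50 bp, 1.78 in the next 3 bins and 1.64 beyond 250 bp. The 2-sided shape of CACTG was present both at peaks of 340 bp (11.0 in those bins against 6.33 within 50 bp) and at narrower peaks (14.9 against 4.47).

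**Figure D3:**
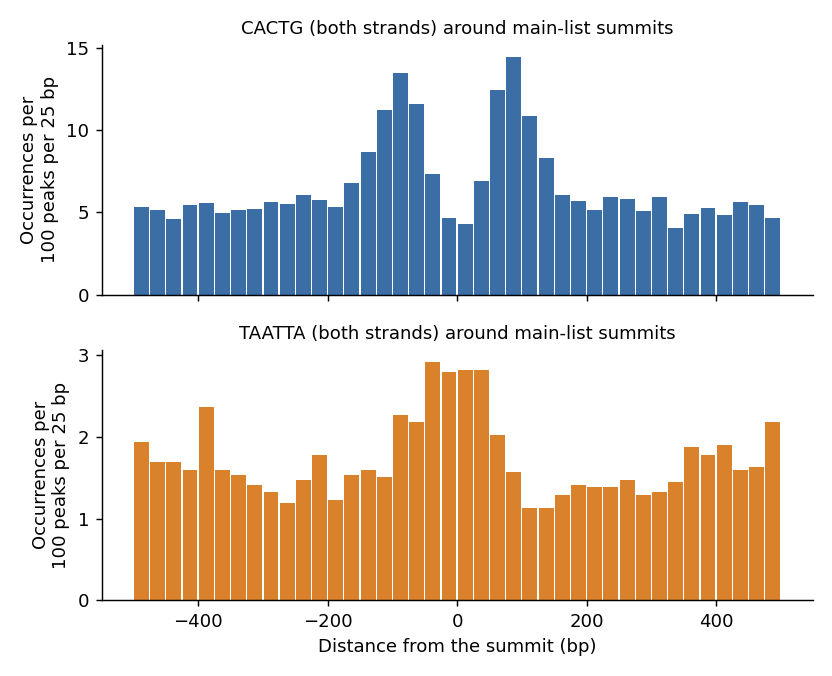
Occurrences of CACTG (top) and TAATTA (bottom), both strands, per 100 main-list peaks in bins of 25 bp against distance from the summit in bp. CACTG is highest 75 to 100 bp from the summit on both sides, at 13.5 and 14.5, and falls to 4.26 to 4.63 beside the summit; TAATTA is highest within 50 bp.

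Heat shock and cytoplasmic ribosomal protein genes were bound more often than other genes, and homeobox, chemosensory receptor, cuticle protein and transfer RNA genes less often. Of the genes with a relaxed peak near a TSS, 1934 of 12941 (14.9%) were bound, and 6 of the 14 lists passed the test. Of 13 tested heat shock genes 8 were bound (61.5%, interval 35.5% to 82.3%, odds ratio 9.14, Fisher's exact adjusted p = 0.00109), over 8 distinct peaks. Hsp22 and Hsp67Bc, named outside the rule, had the same highest signal (142) and may share a peak, so the 8 genes are not independent. Hsp27, a small heat shock protein gene, had a summit at -161 bp with a signal of 882, rank 22 of the list. Hsp26, its neighbour, had one at -119 bp (signal 223), Hsc70-5, a mitochondrial chaperone gene, one at -106 bp (signal 205), and stv, a co-chaperone gene, one at -570 bp (signal 245). Of 67 tested ribosomal protein genes 20 were bound (29.9%, odds ratio 2.44, Fisher's exact adjusted p = 0.00592), among them RpL32 (-135 bp, signal 201), RpS20 (-132 bp, signal 187), RpL34b (-145 bp, signal 180) and RpS19b (-897 bp, signal 395). The ribosomal call was lost in replicate 1's list alone (odds ratio 1.63, Fisher's exact adjusted p = 0.202), among the strongest 1630 peaks (1.33), at an IDR value of 0.001 (1.46) and with a 5000 bp window (1.62).

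Homeobox genes, the family of CG11294 itself, were bound less often than other genes, at 2 of 71 (2.82%, interval 0.776% to 9.70%, odds ratio 0.164, Fisher's exact adjusted p = 0.00592). The 2 were NK7.1 (-709 bp, signal 420) and tin, the heart and visceral mesoderm regulator (-183 bp, 3R 21378702 to 21378845, signal 220). The call was lost in the pooled list (0.534, Fisher's exact adjusted p = 0.194), in replicate 2's list alone (0.429), among the strongest 1630 peaks (0.282) and at IDR values of 0.001 (0.270) and 0.05 (0.430). Chemosensory receptor genes were bound at 2 of 135 (odds ratio 0.0846, Fisher's exact adjusted p = 2.13e-06), namely Or88a (signal 94.9) and Gr32a (signal 68.6). Cuticle protein genes were bound at 3 of 84 (odds ratio 0.210, Fisher's exact adjusted p = 0.00592), namely Cpr62Ba, Cpr64Aa and Cpr72Eb; this call was lost among the strongest 1630 peaks (0.237) and at an IDR value of 0.001 (0.227). Genes of transfer RNAs were bound at 14 of 175 (odds ratio 0.491, Fisher's exact adjusted p = 0.0172) over 12 distinct peaks; the call was lost with a 5000 bp window (odds ratio 0.835) and with a 500 bp window (0.541). The strongest transfer RNA site, at 3R 8669256 to 8669468 (signal 318), was shared by tRNA:Tyr-GTA-1-7 and tRNA:Tyr-GTA-1-8.

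**Figure D4:**
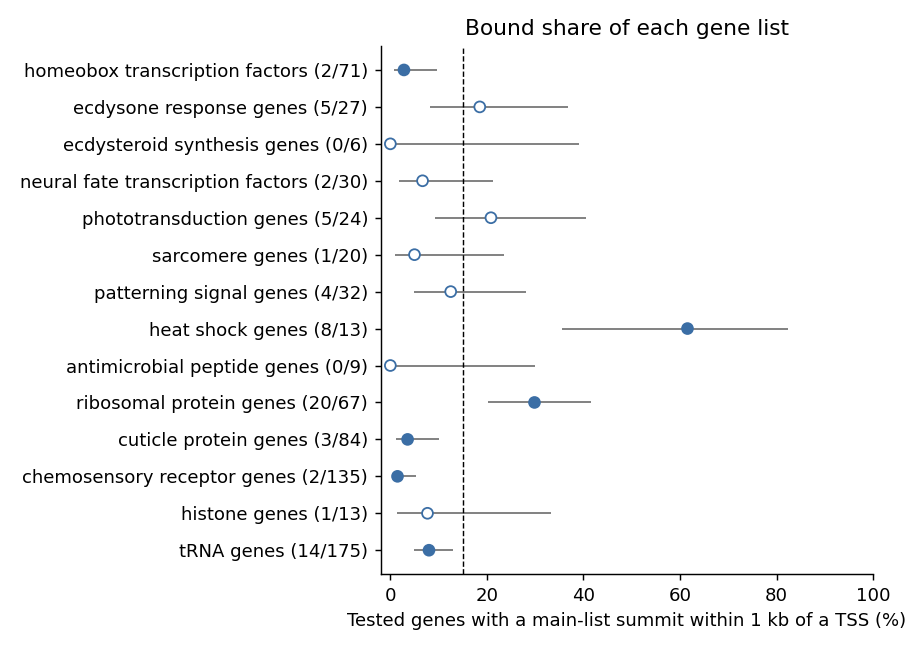
Percentage of tested genes of each list with a main-list summit within 1000 bp of a TSS, with 95% Wilson intervals; bound and tested genes are given in brackets, filled points passed the adjusted test, and the dashed line is the 14.9% over all tested genes. Heat shock genes (8 of 13) and ribosomal protein genes (20 of 67) lie to its right.

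Ecdysone response genes, which answer the steroid pulse that drives the prepupal stage, were bound at 5 of 27 (18.5%, interval 8.18% to 36.7%, odds ratio 1.29, Fisher's exact adjusted p = 0.701). Those 5 were hid, a cell death gene (-305 bp, signal 368), E23, an ABC transporter gene (-225 bp, signal 363), Ldh, the lactate dehydrogenase gene (-179 bp, signal 137), Eip75B, a nuclear receptor gene (33 bp, signal 128), and EcR, the ecdysone receptor gene (-281 bp, signal 91.8). The sites of Eip75B and EcR overlapped no thresholded peak of replicate 2, which also held for those named elsewhere of Hsc70-5, RpS20, Cds, norpA, aos, Cpr72Eb and Gr32a, while those of hb, sty and His2Av overlapped none of replicate 1. The list passed the test with a 5000 bp window (odds ratio 2.76, Fisher's exact adjusted p = 0.0305) and in replicate 1's list alone (2.82, adjusted p = 0.0413).

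The other lists did not pass the test. Phototransduction genes were bound at 5 of 24 (Fisher's exact adjusted p = 0.547), with rdgC, a phosphatase gene (-350 bp, signal 336), and Cds (-85 bp, signal 193) strongest, then inaE (signal 105) and norpA, the phospholipase C gene (signal 88.6). Patterning signal genes were bound at 4 of 32 (Fisher's exact adjusted p = 1), which were spi, an EGF receptor ligand gene (-153 bp, signal 268), aos (signal 147), nkd (signal 133) and sty (signal 79.1). Neural fate genes were bound at 2 of 30, elav, a neuronal RNA-binding protein gene (-265 bp, signal 465), and hb (294 bp, signal 129). The single bound sarcomere gene of 20 was sls, which encodes a titin-like protein (-305 bp, signal 217), and the single bound histone gene of 13 was His2Av (-165 bp, signal 69.9). Histone genes passed the test as less often bound with a 5000 bp window (odds ratio 0.204) and against all annotated genes (0.0667). Of the 126 annotated histone genes only those 13 had a relaxed peak of any rank within 1000 bp of a TSS. The comparison with all annotated genes counts the rest as not bound, and whether they could be measured was not tested. None of the 6 ecdysteroid synthesis genes or 9 antimicrobial peptide genes was bound, which leaves upper limits of 39.0% and 29.9%.

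The genes with the most summits were long. The noncoding gene lncRNA:CR44357 (X 7166451 to 7405797) held 20 and CG1677, which overlaps it, 17. The cell adhesion gene kirre held 16 over 394 kb, and sbb, which encodes a zinc finger protein, 14 over 79.1 kb. CHES-1-like, a forkhead-type gene, held 11 over 27.0 kb, 10 of them found in both replicates. Snoo, Tet and lncRNA:CR44999 held 11 each, and Tlk and heca 10 each. For the other genes, those found in both replicates were 10 for lncRNA:CR44357, 9 for CG1677, 10 for kirre and 9 for sbb. They were 6 for Snoo, 9 for Tet, 8 for lncRNA:CR44999, 5 for Tlk and 4 for heca.

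At the tagged gene itself, CG11294 (FBgn0030058, X 8691820 to 8693620, minus strand), the main list held 0 peaks within 5000 bp, as did the pooled list and replicate 1's list. The list of replicate 2 held 2, the stronger at X 8691076 to 8691371 with a signal of 10.8, rank 2667 of 2709. Copy number of this locus in the transgenic line was not measured, and signal there was not read as binding.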

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

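Of the tests in this part, both were written before their results were seen. Among relaxed peaks of the between-replicate ranked list, 73 on the arms lay past the IDR value of 0.01 but were missing from the thresholded main list; they were counted among the 92304 background peaks and not among the main peaks. They included the third strongest peak of the whole ranked list, with its summit at -1409 bp from the TSS of cbt (2L 480937 to 481251, signal 1402), and strong peaks near Lk6 (signal 992), larp (signal 747) and CG18428 (signal 701); these names were chosen after their values were seen. Of the 73, 45 lay on 3R and 19 on 2L, 29 (39.7%) were at promoters, and 0 overlapped a pooled thresholded peak. One candidate explanation was removal of repeated DNA, but 16.4% of their summits (interval 9.66% to 26.6%) were in soft-masked sequence, against 23.6% in the main list, so most of the missing summits were not at a soft-masked base. The test looked at the summit base alone, and only 91 of 3260 main-list peaks had centre and flank windows free of soft-masked bases. It therefore cannot exclude that a list of repeated regions was used to remove these peaks. Unspecific signal without the CACTG word could not be decided: 45.2% held the word within 100 bp (interval 34.3% to 56.6%), a range that takes in both the background share of 36.6% and the main-list share of 52.6%. What the authors filtered on was not given in the sources used here, and no biological explanation was tested.

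Outside the 6 arms, replicate 1's thresholded list held 12 peaks, 11 on unplaced X contigs and 1 on Y, where replicate 2's list held 1. These peaks entered no comparison.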

How the results depend on the processing

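Over all alternative settings, 108 of 142 values kept their direction and side of the threshold, or lay within 1.5 times of the main count; for single gene lists this was 140 of 168. Promoter share, strength at promoters and replicate overlap did so under all alternatives run. No paired analysis was possible because the design has 1 group. The cause was not tested unless said. The IDR values of 0.001 and 0.05 were chosen after seeing the data.

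Each replicate's list alone gave an X share of 19.8% to 19.9%, a dimer ratio of 1.46 to 2.00, a TAATTA ratio of 1.08 to 1.61, 76 to 294 higher and 248 to 743 lower 6-mers, and 0 to 2 peaks at CG11294. Odds ratios there were 1.41 to 2.45 for patterning genes, 0.843 to 1.53 for ecdysteroid synthesis genes and 0.804 to 1.32 for phototransduction genes.

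The strongest 1630 by signal held an X share of 20.6% and 3 lists past the threshold, with fewer peaks by construction. An IDR value of 0.001 left 1831 peaks, an X share of 20.6% and 3 lists. An IDR value of 0.05 gave 4958 peaks, an X share of 18.1%, 2 lower motifs, 126 higher and 314 lower 6-mers, and a TAATTA difference by strength of 4.60 percentage points, which passed the test as the main difference did not. The pooled list gave an X share of 19.4%, 3 lower motifs and a TAATTA difference of 6.84, and the strongest against the weakest 1630 peaks gave 2.82; both passed the test.

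The dimer ratio no longer passed the test at 1.59 within 50 bp, 1.16 against GC-matched peaks and 1.58 away from promoters. TAATTA stood at 0.927 against GC-matched peaks and 1.14 away from promoters, and passed in neither. Within 50 bp it stood at 1.55 against the flank and passed. GC-matched peaks left 1 higher and 1 lower motif, 31 higher and 36 lower 6-mers. Peaks away from promoters left 4 higher and 3 lower motifs.

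Odds ratios that turned were 1.93 (pooled), 1.01 (strongest 1630), 1.76 (5000 bp), 1.02 (all genes) and 1.80 (IDR 0.05) for patterning genes, 0.889 (strongest 1630) for phototransduction genes, and 1.97 (IDR 0.05) for ecdysteroid synthesis genes; none passed the test. Unknown depth limits what the weak peaks can show.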

Other observations

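The tests named as such in this part were chosen after the result was seen for promoter sequence, the held-out words, the GC-matched share of CACTG, orientation, the A and T only words, the mitochondrial list and gene bodies; those on repeated DNA, on both sides of a summit and on GC-matched TAATTA were written before. Mitochondrial ribosomal protein genes were bound at 12 of 49 (24.5% against 14.9%, odds ratio 1.85, Fisher's exact adjusted p = 0.149), which did not pass the test, although mRpL41, mRpS10 and mRpS23 had signals of 1292, 1129 and 1081, ranks 5, 9 and 11 of the list. Over gene bodies with 2000 bp upstream, homeobox genes held a summit in 12 of 90, against 29.1 on average in 10000 draws of protein-coding genes of like length (adjusted p = 0.00260, permutation test). Chemosensory receptor genes held one in 5 of 179 (21.8 drawn, permutation adjusted p = 0.00260) and sarcomere genes in 2 of 28 (7.75 drawn, adjusted p = 0.0307). Cuticle protein genes, in 5 of 119 (11.7 drawn, permutation adjusted p = 0.0750), did not pass this test, while ribosomal protein genes (21 of 92, 9.44 drawn, adjusted p = 0.00520) and heat shock genes (8 of 20, 3.04 drawn, adjusted p = 0.0307) held more.

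Several ecdysone response genes held summits along their length, and those named here were chosen after their values were seen. Hr4 held 9 (6 of them found in both replicates), ftz-f1 8 (1 in both), Eip75B 6 (3 in both) and Hr3 5 (5 in both). Gene length may account for this: 15 of 29 genes of the list held a summit, no more than the upper limit of 15 from length-matched draws (range 6 to 15 for 95% of draws, mean 10.6, adjusted p = 0.171, permutation test).

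For CACTG words near summits, promoter sequence alone would not give the ratio of 1.88 at peaks with no TSS within 500 bp, and repeated DNA would not give 1.59 at the 91 peaks whose windows held no soft-masked base (exact McNemar p = 0.00552). These were 91 of 3260 peaks, and a part played by repeated DNA at the others was not excluded. At peaks with a TSS within 500 bp the ratio was lower, at 1.39 (46.9% against 33.6%). The share with CACTG did not differ detectably with strength, at 52.8% of the 815 strongest and 49.8% of the 815 weakest peaks (Fisher's exact p = 0.254). Sequence shared by all relaxed peaks was argued against by a share 1.65 times that of GC-matched background summits. Chance choice of the word was argued against by a split of the arms: of the 6 called 6-mers of largest ratio on 2L and 3L alone, ACAGTG and ACACTG held CACTG, and on the other arms (1937 peaks) their ratios were 2.55 and 2.43 (exact McNemar adjusted p = 2.54e-30 and 6.01e-25). Among 8-mers, ATTTAAAA had the largest difference in count relative to its total on 2L and 3L (ratio 2.23 on the other arms) and says nothing on CACTG, while CACTGAGA (99 summits against 8 flanks there, ratio 12.4) was picked because it holds a word found on all arms and is not independent evidence. What brought these sites into the immunoprecipitate was not tested, and recovery by the antibody without the tagged protein stays open, since no control was analysed here.

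The word may also be placed in pairs. CACTG words in the 3 bins of 25 bp from 50 bp outward on the left and right of one summit went together at 418 peaks (12.8% against 10.1% if independent, odds ratio 1.74, Fisher's exact p = 3.49e-12), and not 500 bp to the left (odds ratio 0.955, p = 0.813). Independent placement at the same rate in all peaks would not give this. Peaks that differ in how often they hold the word could give it without pairing, and the test cannot tell these apart. The left side held the word at 35.1% of peaks with no TSS within 500 bp and 25.3% of the others, with odds ratios of 1.60 and 1.97 within these groups. At summits with no TSS within 500 bp, orientation differed between the sides, with 449 CACTG and 315 CAGTG on the left against 322 and 434 on the right (odds ratio 1.92, Fisher's exact p = 3.55e-10); this was not seen at promoter summits (odds ratio 0.761, p = 0.0874).

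The excess of TAATTA over the flank is consistent with AT-rich composition, since 100% of the other 35 words of A and T had a higher ratio (median 1.68 against 1.35). For recognition of TAATTA by the homeodomain, a GC-matched ratio above 1.2 was set beforehand, and a ratio of 1 or less was set against it. The ratio was 0.927 with a 95% interval of 0.845 to 1.02. That interval lies below 1.2, so TAATTA had no excess of that size over these background summits within 100 bp. The background was drawn from relaxed peaks of the same immunoprecipitation, of which 73 lay past the IDR value of 0.01. Such peaks may include weaker sites of the same protein, so the test cannot decide on recognition. The interval reaches above 1, so a smaller excess was not excluded, and it covers TAATTA alone and not the other homeodomain sites.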
